A study of Mus musculus with 112 samples.

How the data were processed

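Messenger RNA of the liver, PFC and amygdala of saline-, tesaglitazar-, fenofibrate- and bezafibrate-treated mice was measured on 112 Illumina MouseWG-6 arrays of 45281 probes. The signals came as 120 array columns, of which 8 match no sample and were not used. Each remaining column was matched to its sample by the treatment, tissue and mouse number in its name, and treatment groups came from the sample labels alone. The liver had 37 arrays, the PFC 38 and the amygdala 37, in groups of 9 or 10 mice.

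Per the file headers, the deposited signal intensities are the summarized probe signals of each array before normalization, with the detection p-value of each probe on that array beside them. The deposited log2 values of each sample were quantile normalized within a tissue by the authors, which was checked on the values (sorted values of different arrays differ by at most 0.00318 in the liver, 0.00347 in the PFC and 7.4e-04 in the amygdala). The R package lumi is the only tool the notes of the study name, and its version and the steps it was used for are not given in the sources used here. Log2 signals correlated with the log2 values of the authors at 0.992 to 0.999 per array in the liver, 0.990 to 0.999 in the PFC and 0.989 to 0.997 in the amygdala.

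All fits used the deposited intensities in R 4.3.3 with limma 3.58.1 and data.table version 1.17.8. Within each tissue, neqc corrected the background from the detection p-values, quantile normalized the arrays and took log2. Probes were named from the table of probes and gene symbols of the array. Of all probes 34885 carry 1 symbol, 18 several and 10378 none, and the probes with several or none were not analysed. Of the 1-symbol probes, 34807 matched a mouse RefSeq gene by gene ID, with 0 symbols changed. A probe was kept when its detection p-value was under 0.01 on at least 9 arrays of the tissue, the size of the smallest group, and each gene was represented by its kept probe of highest mean. This left 9291 genes in the liver, 10712 in the PFC and 11064 in the amygdala. Dim genes near background could not be followed, and the number of arrays limits the precision.

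One linear model per tissue held the 4 treatment groups, and eBayes gave moderated tests, 2-sided, for each agonist against saline and for each pair of agonists. Benjamini-Hochberg adjustment ran over the genes of a comparison, and adjusted p under 0.05 counts as passing. Differences in effect between tissues came from 1 joint fit of the 12 groups after neqc of all 112 arrays together, over 11245 genes for PFC against amygdala and 12118 for liver against brain. Confidence intervals are at 95 percent. Where every array of a group lacked a detected signal, the fold is given as a lower bound.

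Lists of genes and of cell type markers were fixed beforehand, 22 gene lists for the liver and 21 for each brain region, beside 9 marker lists for the liver and 10 for each brain region. In the liver 722 of 787 listed genes were named on the array and 632 tested, in the PFC 663 of 726 and 503, and in the amygdala 663 of 726 and 507. Of the marker lists 5 could be tested in the liver (72 of 134 markers), 9 in the PFC (110 of 164) and 10 in the amygdala (119 of 164). Each list was tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a tissue and the 3 agonists. The shared response of 2 agonists is the correlation of their log2 changes across genes, set beside its value by chance with shared saline arrays.

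Named genes follow a rule set in advance. For each agonist against saline it takes the 6 largest rises and 4 largest falls among genes that pass, or the 3 genes of smallest p where none passes. From each list it takes up to 4 members of smallest p, and from each pair of agonists and each difference between tissues the 4 largest per direction. It adds the PPAR genes and target genes, among them Acot1, Cyp4a10, Cyp4a14, Pdk4, Angptl4, Cpt1a, Plin2, Cd36, Fabp4, Cidea, Cidec and Vnn1. Of these, Cyp4a10 was not analysed here, Cpt1a, Cd36, Fabp4 and Vnn1 were not detected on enough arrays of any tissue, and Ppara, Cyp4a14 and Cidec were tested in the liver alone. Other genes the rule adds are not reported here.

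The mouse number from 1 to 40 was taken to join tissues of 1 animal. As a check, residuals of the same number in different tissues were correlated across genes, and their mean r was 0.0439 for liver and PFC (36 mice), -0.00148 for liver and amygdala (34 mice) and 0.0589 for PFC and amygdala (35 mice), against -0.00485, 1.4e-04 and -0.00649 for other mice of the treatment. The fits treat arrays as independent, and a fit with the mouse as a block was an alternative.

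The fits were tested on simulated data in which 50 genes changed at each size. Sizes ran up to a log2 change of 2, and noise was drawn independently for each gene. The larger changes ease the adjusted threshold for the smaller ones, so the shares recovered do not give the power for few changed genes. At log2 changes of 0.5 and 1, the liver fit of 9291 genes recovered 72 and 100 percent for tesaglitazar, 78 and 94 percent for fenofibrate and 72 and 96 percent for bezafibrate. The PFC fit of 10712 genes recovered 92 and 100 percent for tesaglitazar, 92 and 100 percent for fenofibrate and 86 and 100 percent for bezafibrate. The amygdala fit of 11064 genes recovered 84 and 94 percent for tesaglitazar, 78 and 98 percent for fenofibrate and 88 and 96 percent for bezafibrate.

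Alternatives changed 1 choice at a time. They were no background correction, normalization of the tissues together or apart, the processed values of the authors, no detection filter, the mean of the probes of a gene, variance trend and robust priors, the lower and upper mouse numbers as a block, the mouse as a block, array weights and fits of only the groups compared. Added after the values were seen were fits without mice 4 and 6, without PFC fenofibrate mouse 20, without each PFC saline or fenofibrate array in turn, and with the share of probes detected or the mean of the oligodendrocyte markers as a covariate.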

Results

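Messenger RNA was measured on Illumina MouseWG-6 arrays in the liver, the prefrontal cortex (PFC) and the amygdala of male C57BL/6J mice dosed by mouth for 8 days. The mice received saline, tesaglitazar at 1.5 mg/kg, fenofibrate at 150 mg/kg or bezafibrate at 75 mg/kg. All 3 drugs activate peroxisome proliferator-activated receptors (PPARs), nuclear receptors that switch on genes of fatty acid use. Fenofibrate acts mainly on PPAR-alpha, tesaglitazar on PPAR-alpha and PPAR-gamma, and bezafibrate on all members of the family. Each array held 1 tissue of 1 mouse. The liver gave 10 saline, 9 tesaglitazar, 9 fenofibrate and 9 bezafibrate arrays, the PFC 10, 9, 9 and 10, and the amygdala 9, 10, 9 and 9. The median signal per array ran from 83.3 to 102 in the liver, from 88.4 to 111 in the PFC and from 92.1 to 117 in the amygdala. The share of probes detected ran from 31.4 to 36.6 percent in the liver, from 36.6 to 44.4 percent in the PFC and from 40.8 to 44.6 percent in the amygdala. The number of arrays limits the precision.

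A pair of liver libraries stood with the other group. The library labelled saline mouse 4 had a log2 intensity of 10.63 for Cidea, a lipid droplet gene, where the other 9 saline livers lay between 4.2 and 4.42 and the other 8 tesaglitazar livers between 8.07 and 11.76. The library labelled tesaglitazar mouse 6 had 4.18. Hsd3b5, a steroid reductase gene of the male liver, gave 4.46 in the library labelled saline mouse 4 and 11.40 in the library labelled tesaglitazar mouse 6, against 11.74 to 12.95 in the other saline livers and 4.17 to 5.57 in the other tesaglitazar livers. Every array kept its label in the comparisons. Values "without mice 4 and 6" leave out all arrays with those labels, a choice made after the values were seen.

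**Figure D1:**
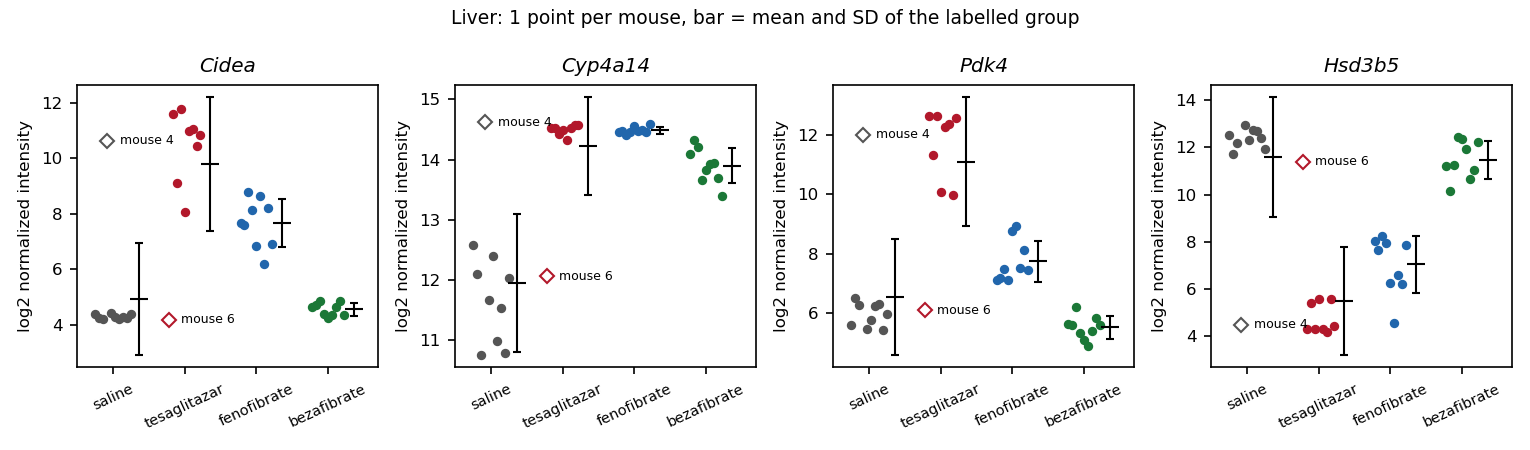
Log2 intensity of Cidea, Cyp4a14, Pdk4 and Hsd3b5 in each liver by treatment (9 or 10 mice per group). Points are mice, bars the mean and SD, and open diamonds the libraries labelled saline mouse 4 and tesaglitazar mouse 6, which lie at the level of the other group in all 4 panels.

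The first comparison asks what tesaglitazar changed in the liver. Genes for fatty acid binding, storage and oxidation were among the largest rises, and genes for steroid and drug metabolism among the largest falls. Fabp3, the gene of the heart-type fatty acid-binding protein, rose by 5.82 ± 0.82 (SE) on the log2 scale, or 56.5-fold (limma adjusted p = 2.0e-06, 9 against 10 livers). Cyp2b9, a cytochrome P450 gene that is mainly active in female livers, rose by 5.34 ± 0.83 (adjusted p = 4.6e-06). Cidea rose by 4.84 ± 0.71, the acyl-CoA thioesterase gene Acot2 by 4.71 ± 0.61, Ly6d by 4.65 ± 0.62 and Pdk4, whose product holds back pyruvate oxidation, by 4.54 ± 0.66, with adjusted p between 1.6e-06 and 2.6e-06. Hsd3b5 fell by 6.11 ± 0.81 (adjusted p = 1.6e-06). Serpina12, which encodes vaspin, fell by 4.90 ± 0.78 (adjusted p = 6.1e-06), and the P450 genes Cyp2c50 and Cyp2c37 fell by 4.30 ± 0.63 and 4.13 ± 0.63 (adjusted p = 2.6e-06 and 3.6e-06). Of 9291 genes, 2188 rose and 2197 fell, and without mice 4 and 6 the counts were 2598 and 2644. Fabp3 then rose at least 118-fold against a saline group with no detected signal, Cidea at least 51.7-fold and Ly6d at least 48.8-fold against such a group, Cyp2b9 by 6.81, Acot2 by 5.92 and Pdk4 by 5.77. Hsd3b5 then fell by 7.64, Serpina12 by 6.17, Cyp2c50 by 5.37 and Cyp2c37 by 5.17. Hsd3b5 was detected in 4 of 9 tesaglitazar livers, or 3 of 8 without mouse 6, so its falls are read against values near background. Pparg itself fell by 0.84 ± 0.17 (adjusted p = 1.1e-04), while Ppara (0.05 ± 0.20, adjusted p = 0.861) and Ppard (-0.02 ± 0.07, adjusted p = 0.884) did not pass.

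Lists of genes fixed before the data were examined show which pathways moved with tesaglitazar in the liver. Among 29 core PPAR targets 25 rose and 1 fell (median log2 change 1.97, camera adjusted p = 1.8e-11), with Acot1 at 3.24, Angptl4 at 1.19 and Cyp4a14, near the top of the signal range, at 2.28. Fatty acid uptake and lipid droplet genes rose (27 of 31, 3 fell, adjusted p = 3.3e-11), among them Vldlr at 3.37, Gpat3 at 3.36 and Slc27a1 at 3.11. Mitochondrial beta-oxidation and ketogenesis genes rose (27 of 32, 2 fell, adjusted p = 1.2e-10), such as Acadm at 0.98. Cell cycle genes rose (23 of 27, 1 fell, adjusted p = 4.6e-10), with Cdca3 at 1.62 and Cdk1 at 1.36. Fatty acid synthesis genes rose (15 of 23, 3 fell, adjusted p = 3.3e-04), with Me1 at 2.32 and Fads2 at 2.02. Acute phase, complement and coagulation genes fell (47 of 61, 5 rose, adjusted p = 1.0e-12), as C8b at -2.53 and C1s1 at -1.92 did. Genes expressed more in one sex fell (21 of 26, 2 rose, adjusted p = 6.4e-09), Hsd3b5 the most. Without mice 4 and 6 Acot1 stood at 4.14, Vldlr at 4.21, Gpat3 at 4.17, Slc27a1 at 3.92 and C8b at -3.15. Each of these 7 lists had adjusted p = 0.246 with an estimated correlation.

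Peroxisomal beta-oxidation genes also rose with tesaglitazar in the liver (23 of 34, 2 fell, adjusted p = 1.2e-07, and adjusted p = 0.26 with an estimated correlation), with Acot3 at 4.40 and Ehhadh, the peroxisomal bifunctional enzyme gene, at 3.70. Oxidative phosphorylation genes rose slightly (36 of 65, 2 fell, median 0.24, adjusted p = 6.0e-07), led by Ndufab1 at 1.31 and Cycs at 0.84, and cholesterol synthesis genes rose (11 of 17, 1 fell, adjusted p = 5.7e-04), as Lss did at 1.03. Circadian clock genes fell (7 of 16, 1 rose, adjusted p = 0.0477), with Tef at -0.69 and Dbp at -0.66. These 3 lists had adjusted p = 0.348 with an estimated correlation. Amino acid catabolism and urea cycle genes fell (29 of 42, 2 rose, adjusted p = 1.2e-07, and adjusted p = 0.307 with an estimated correlation), as Gnmt did at -1.74 and Cps1 at -1.15. Bile acid synthesis and transport genes fell (13 of 21, 3 rose, adjusted p = 0.00534, and adjusted p = 0.26 with an estimated correlation), with Slco1a4 at -2.71 and Abcb11, the bile salt export pump gene, at -1.17. Hepatocyte markers fell beside them (8 of 14, none rose, adjusted p = 0.00795, and adjusted p = 0.668 with an estimated correlation), among them Asgr2 at -0.83 and Alb at -0.81. Without mice 4 and 6 Acot3 stood at 5.59, Ehhadh at 4.70 and Slco1a4 at -3.52. Adjusted over the list alone, the counts were 28 up for uptake, 12 up for cholesterol, 24 up for cell cycle, 37 up for oxidative phosphorylation, 48 down for acute phase and 14 down for bile acid genes, and the other lists that passed kept the counts given.

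**Figure D2:**
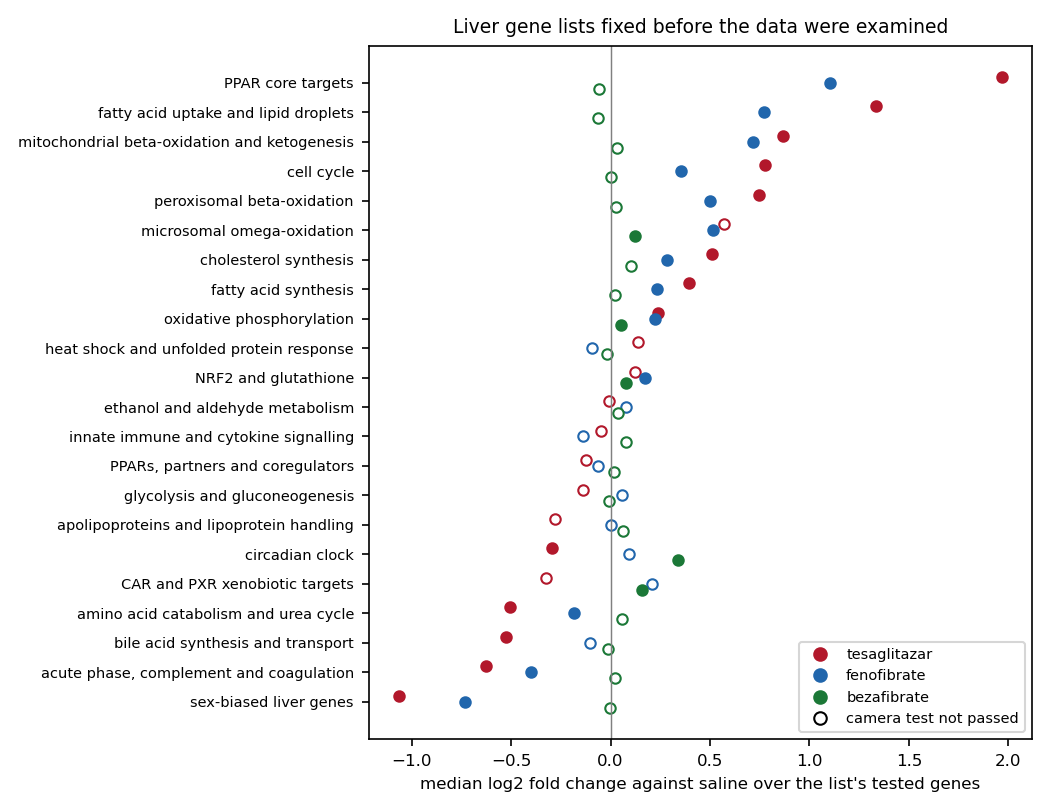
Median log2 change of each gene list in the liver against saline, for tesaglitazar, fenofibrate and bezafibrate. Filled points passed camera at adjusted p under 0.05, and core PPAR targets reach 1.97 with tesaglitazar and 1.10 with fenofibrate.

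Fenofibrate in the liver had P450, acyl-CoA thioesterase and peroxisomal genes among its largest rises. Cyp2b9 rose by 5.47 ± 0.83 (SE) on the log2 scale, 44.5-fold (limma adjusted p = 1.2e-05, 9 against 10 livers). Acot3, a peroxisomal acyl-CoA thioesterase gene, rose by 4.50 ± 0.62 (adjusted p = 3.7e-06), the keratin gene Krt23 by 4.22 ± 0.60 (adjusted p = 4.7e-06) and Ehhadh by 3.90 ± 0.52 (adjusted p = 2.3e-06). Cyp4a31, a fatty acid omega-hydroxylase gene, rose by 3.88 ± 0.50 (adjusted p = 1.4e-06), and Acot2 by 3.76 ± 0.61 (adjusted p = 3.1e-05). Serpina12 fell by 4.89 ± 0.78 (adjusted p = 2.5e-05), Hsd3b5 by 4.57 ± 0.81 (adjusted p = 9.4e-05), the protease inhibitor gene Serpina1e by 3.19 ± 0.62 (adjusted p = 2.4e-04) and Sdr9c7 by 2.42 ± 0.35 (adjusted p = 7.7e-06). In all 1267 genes rose and 1219 fell of 9291, and without mice 4 and 6 the counts were 1751 and 1803, with Cyp2b9 at 6.18, Serpina12 at -5.51, Hsd3b5 at -5.36 and Cidea at least 7.36-fold higher than a saline group with no detected signal. Acot1 rose by 3.28, Cyp4a14, near the top of the signal range, by 2.54, Cidec by 2.60, Cidea by 2.73, Plin2 by 1.12 and Angptl4 by 0.75, each with adjusted p at or below 0.00973. Pdk4 (1.18 ± 0.66, adjusted p = 0.186) and Pparg (-0.27, adjusted p = 0.235) passed only without mice 4 and 6, at 1.79 (adjusted p = 1.4e-05) and -0.40 (adjusted p = 0.0235).

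Fenofibrate moved most of the same lists in the liver. Core PPAR targets rose (22 of 29, median 1.10, camera adjusted p = 1.8e-12), as did mitochondrial beta-oxidation genes (22 of 32, adjusted p = 1.8e-13), uptake and lipid droplet genes (22 of 31, adjusted p = 2.3e-10), none of whose members fell, and peroxisomal beta-oxidation genes (19 of 34, 1 fell, adjusted p = 6.5e-11). NRF2 and glutathione genes rose too (15 of 30, 2 fell, adjusted p = 2.7e-04), with Gstt2 at 1.57 and Srxn1 at 0.54. These 5 lists had adjusted p = 0.246 with an estimated correlation. Omega-oxidation genes rose (7 of 12, 1 fell, adjusted p = 9.2e-04, and adjusted p = 0.195 with an estimated correlation), with Cyp4a12b at 1.56 and with Cyp4f14 against the trend at -1.82. Oxidative phosphorylation genes rose (29 of 65, 1 fell, median 0.22, adjusted p = 2.7e-10, and adjusted p = 0.26 with an estimated correlation), for example Ndufab1 at 1.09. Smaller rises were those of cell cycle genes (11 of 27, 1 fell, adjusted p = 5.6e-05, and adjusted p = 0.385 with an estimated correlation), cholesterol synthesis genes (7 of 17, adjusted p = 9.2e-04, and adjusted p = 0.348 with an estimated correlation) and fatty acid synthesis genes (11 of 23, 2 fell, adjusted p = 0.00762, and adjusted p = 0.326 with an estimated correlation). Cdk1 rose by 0.70, Hsd17b7 by 0.59 and Fads2 by 1.73. Acute phase genes fell (36 of 61, 2 rose, adjusted p = 4.9e-10, and adjusted p = 0.307 with an estimated correlation), as did sex-biased genes (15 of 26, 1 rose, adjusted p = 9.9e-07, and adjusted p = 0.308 with an estimated correlation). C8b stood at -1.59 and Fetub at -0.67. Amino acid catabolism genes fell (13 of 42, 2 rose, adjusted p = 0.00485, and adjusted p = 0.626 with an estimated correlation), with Cps1 at -0.78, and so did hepatocyte markers (6 of 14, adjusted p = 0.00928, and adjusted p = 0.668 with an estimated correlation). Adjusted over the list alone, 21 peroxisomal, 37 oxidative phosphorylation, 16 NRF2 and 13 cell cycle genes rose and 41 acute phase, 16 sex-biased, 7 hepatocyte, 4 NRF2 and 2 omega-oxidation genes fell, and the other lists that passed kept the counts given.

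Bezafibrate in the liver changed clock genes and, of the PPAR targets named here, Cyp4a14 alone with all arrays. Usp2, a deubiquitinase gene with a daily rhythm, rose by 2.07 ± 0.32 (SE) on the log2 scale, 4.19-fold (limma adjusted p = 1.6e-04, 9 against 10 livers), and Ciart, which encodes a circadian repressor, by 2.01 ± 0.24 (adjusted p = 2.2e-06). Cyp4a14, a fatty acid omega-hydroxylase gene and a classical PPAR-alpha target, rose by 1.95 ± 0.32 (adjusted p = 3.7e-04). Mfsd2a, the gene of a lysophosphatidylcholine transporter, rose by 1.85 ± 0.33 (adjusted p = 7.8e-04), the clock-driven deadenylase-like gene Noct by 1.33 ± 0.35 (adjusted p = 0.0374) and the neuregulin gene Nrg4 by 1.17 ± 0.12 (adjusted p = 4.8e-08). Tubb2b fell by 1.35 ± 0.25 (adjusted p = 0.00138), Slc30a10, a manganese exporter gene, by 1.05 ± 0.25 (adjusted p = 0.0140), Tmie by 1.02 ± 0.19 (adjusted p = 0.00125) and Elovl3, a fatty acid elongase gene, by 1.02 ± 0.14 (adjusted p = 2.6e-05). Only 76 genes rose and 82 fell of 9291, and without mice 4 and 6 the counts were 189 and 191. Acot1 (0.75, adjusted p = 0.525), Ehhadh (1.86, adjusted p = 0.0579) and Cyp4a31 (1.71, adjusted p = 0.0697) passed only without mice 4 and 6, at 1.16 (adjusted p = 1.1e-06), 2.36 (adjusted p = 1.1e-08) and 2.18 (adjusted p = 2.6e-10). Pdk4 (-1.04, adjusted p = 0.55), Angptl4 (0.05, adjusted p = 0.968), Plin2 (-0.33, adjusted p = 0.759), Cidea (-0.37, adjusted p = 0.894) and Cidec (-0.14, adjusted p = 0.96) did not pass. They did not pass without mice 4 and 6 either, with Pdk4 at -0.43, Angptl4 at 0.21, Plin2 at -0.04 and Cidec at 0.38, and Cidea had no detected signal in saline livers.

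Circadian clock genes were the list bezafibrate moved most in the liver (7 rose and 2 fell of 16, camera adjusted p = 1.8e-05, and adjusted p = 0.228 with an estimated correlation). Per2 rose by 1.10, Per1 by 1.08, Tef by 0.81 and Dbp by 0.78, while the activator genes Arntl and Clock fell by 1.01 and 0.62. Omega-oxidation genes rose as a list (adjusted p = 0.0108, and adjusted p = 0.246 with an estimated correlation), although only Cyp4a14 of 12 members passed over all genes. The other lists that passed were targets of the drug receptors CAR and PXR (2 of 25 rose, Alas1 at 0.82 and Nr1i2 at 0.40, adjusted p = 0.0148), NRF2 and glutathione genes (0 of 30 at limma adjusted p under 0.05, median 0.08, adjusted p = 0.0369), both with adjusted p = 0.348 with an estimated correlation, and oxidative phosphorylation genes (median 0.05, adjusted p = 0.0128, and adjusted p = 0.754 with an estimated correlation), of which only Uqcrc2 passed, at -0.22. Core PPAR targets did not pass as a list with all arrays, their median (-0.06) and mean (0.01) differing in sign. That saline group holds the library labelled mouse 4. Its difference from the other saline livers followed the tesaglitazar effect (r = 0.931 across genes), which raises the saline mean of PPAR targets. The list result therefore does not show that bezafibrate left these targets unmoved. Adjusted over the list alone, 8 clock and 3 omega-oxidation genes rose and the other counts stayed. With all arrays none of the 31 liver list tests that passed with the preset correlation held with an estimated one, and without mice 4 and 6 the number that passed with an estimated one was 14, including core PPAR targets with tesaglitazar (adjusted p = 8.3e-04) and fenofibrate (adjusted p = 5.7e-04).

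The agonists were also compared with each other in the liver, at doses that differ, so that compound and dose cannot be separated. Between tesaglitazar and fenofibrate, Pdk4 was 3.36 ± 0.68 (SE) higher on the log2 scale with tesaglitazar (limma adjusted p = 8.0e-04, 9 against 9 livers), Fabp3 3.05 ± 0.84 higher (adjusted p = 0.00955), the stress gene Nupr1 2.76 ± 0.59 higher (adjusted p = 0.00131) and the chemokine receptor gene Cxcr1 2.49 ± 0.48 higher (adjusted p = 5.6e-04). The difference was -3.32 ± 0.65 for Cyp2c50, -3.18 ± 0.64 for Cyp2c37, -2.52 ± 0.33 for Usp2 and -2.50 ± 0.39 for BC048644 (adjusted p at most 8.3e-04). In total 893 genes were higher and 889 lower with tesaglitazar, or 2969 together without mice 4 and 6. Cyp4a14 lay near the top of the signal range in both groups (mean 14.49 with fenofibrate, 14.33 to 14.58 in the tesaglitazar livers other than mouse 6), so that no difference could be read there. Acot1 did not differ, with a 95 percent confidence interval of -0.99 to 0.89, though without mice 4 and 6 Acot1 was 0.45 higher with tesaglitazar (adjusted p = 0.0148). The tesaglitazar mean of Acot1 was then 14.51, also near the top of the signal range, so that this size is uncertain. Cidec, Plin2 and Angptl4 also passed only without mice 4 and 6, being 1.65, 1.19 and 0.64 higher (adjusted p = 3.0e-08, 1.3e-07 and 0.00106), and Pdk4 was then 3.98 higher and Fabp3 3.88 higher, with Cyp2c50 at -3.93 and Cyp2c37 at -3.80. Tesaglitazar exceeded bezafibrate at 2178 genes and lay below it at 2247. Pdk4 was 5.58 ± 0.68 higher, Cidea 5.21 ± 0.73 higher, Fabp3 at least 64.5-fold higher and Ly6d at least 30.1-fold higher, since bezafibrate livers had no detected signal for Fabp3 and Ly6d. Hsd3b5 (-5.99 ± 0.84), Cyp2c50 (-4.49 ± 0.65), Cyp2c37 (-4.31 ± 0.64) and Serpina1e (-4.16 ± 0.63) were lower (adjusted p at most 2.4e-06). Cidea was detected in only 2 of 9 bezafibrate livers and Hsd3b5 in 4 of 9 tesaglitazar livers, so both sizes are read against values near background. Without mice 4 and 6 Pdk4 was 6.20 and Cidea 5.91 higher, Fabp3 at least 115-fold and Ly6d at least 47.6-fold higher, and Hsd3b5 stood at -6.73, Cyp2c50 at -5.10 and Cyp2c37 at -4.92.

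The 2 fibrates differed at 2019 genes in the liver, 1027 higher and 992 lower with fenofibrate, which was given at 150 against 75 mg/kg. Cyp2b9 was 5.17 ± 0.85 (SE) higher on the log2 scale (limma adjusted p = 1.5e-04, 9 against 9 livers), Acot2 3.80 ± 0.62 higher, Ly6d at least 12.7-fold higher and Fabp3 at least 7.78-fold higher. Hsd3b5 (-4.45 ± 0.84), Serpina12 (-3.69 ± 0.80), Serpina1e (-3.32 ± 0.63) and Nnmt, a nicotinamide methyltransferase gene (-2.32 ± 0.56), were lower with fenofibrate (adjusted p at most 0.00311). Acot1 was 2.53 ± 0.46 higher (adjusted p = 3.4e-04) and Cidea 3.10 ± 0.73 higher (adjusted p = 0.00262), whereas the difference in Cyp4a14, whose signal was near the top of the range with fenofibrate, had an interval of -0.07 to 1.26 and passed only without mice 4 and 6 (0.59, adjusted p = 0.00731). The size of the Cyp4a14 difference may be held down by the top of the range. Cyp2b9 was detected in only 4 and Cidea in only 2 of 9 bezafibrate livers, so their sizes are read against values near background.

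Tesaglitazar and fenofibrate shared much of their liver response. Of the genes past the threshold, 976 rose with both, against 298.4 for independent lists, 908 fell with both (288.3) and 15 went opposite ways (586.7). Acot2, Ehhadh and Cyp2b9 are among those that rose with both, and Serpina12 and Hsd3b5 among those that fell with both. Fenofibrate and bezafibrate shared 48 rises, Usp2 and Ciart among them, and 53 falls, Elovl3 among them, with no gene in opposite directions (10.4 and 10.8 for independent lists). The numbers for independent lists do not allow for the saline livers that the comparisons share. Tesaglitazar and bezafibrate shared 17 rises and 26 falls (17.9 and 19.4), with 32 genes opposite, and without mice 4 and 6 they shared 123 rises and 125 falls (52.9 and 54.4). Across genes, which are not independent replicates, the log2 changes of tesaglitazar and fenofibrate correlated at r = 0.816 ± 0.0637 (jackknife SE). Chance gave 0.487 on average (-0.0149 to 0.849 over 100 draws), since both share the saline livers, so the r by itself does not exceed chance. The covariance of the log2 changes, 0.164, did lie above the highest by chance, 0.0266. Separate saline livers for each agonist gave r = 0.762. The r was 0.351 ± 0.273 (jackknife SE) for fenofibrate and bezafibrate (0.488 by chance) and 0.0214 ± 0.368 for tesaglitazar and bezafibrate (0.437 by chance). These errors are too wide to tell either value from chance. Without mice 4 and 6 the r was 0.605 ± 0.0610 and 0.370 ± 0.0607 in the same order (0.509 and 0.479 by chance). The covariances of 0.0480 and 0.0448 then lay above the highest by chance, 0.0124 and 0.0176.

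In the PFC, fenofibrate raised Dbp and other clock genes and lowered Nptx2 and the myelin gene Opalin, by less than 1 on the log2 scale. Dbp, a clock output gene, rose by 0.41 ± 0.05 (SE; limma adjusted p = 3.6e-05, 9 against 10 mice), with all 9 fenofibrate arrays (11.65 to 11.87) above all 10 saline arrays (11.23 to 11.55). Per2 rose by 0.54 ± 0.09 (adjusted p = 9.6e-04), Ciart by 0.46 ± 0.09 (adjusted p = 0.00431) and Per1 by 0.40 ± 0.10 (adjusted p = 0.0146). The largest rises were those of Gm7609 (0.75 ± 0.14, adjusted p = 0.00229), Pisd-ps3 (0.68 ± 0.21, adjusted p = 0.0452), Erich5 (0.67 ± 0.11, adjusted p = 7.7e-04), the dystroglycan gene Dag1 (0.64 ± 0.14, adjusted p = 0.00587), the imprinted noncoding RNA gene Rian (0.64 ± 0.17, adjusted p = 0.0233) and the RNA helicase gene Ddx3x (0.63 ± 0.18, adjusted p = 0.0319). Nptx2, the gene of a synaptic pentraxin that neuronal activity induces, fell by 0.62 ± 0.11 (adjusted p = 0.00184) with every fenofibrate array (8.59 to 9.47) below every saline array (9.55 to 9.93). The metallothionein gene Mt3 fell by 0.56 ± 0.13 (adjusted p = 0.0105), the oligodendrocyte gene Opalin by 0.55 ± 0.14 (adjusted p = 0.0134) and Zfp763 by 0.53 ± 0.11 (adjusted p = 0.00431). Of 10712 genes 207 rose and 471 fell, and the total of 678 became 153 when only these groups were fitted, 397 without the array labelled saline mouse 4, 377 without saline mouse 3, 388 without fenofibrate mouse 38 and 449 without fenofibrate mouse 40. Pisd-ps3 and Ddx3x did not pass without mouse 4 (adjusted p = 0.0936 and 0.0713).

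The circadian clock list rose with fenofibrate in the PFC (5 of 17 over all genes, camera adjusted p = 2.0e-05, and adjusted p = 0.00232 with an estimated correlation). Cholesterol synthesis genes fell (3 of 16, adjusted p = 0.0111, and adjusted p = 0.419 with an estimated correlation), namely Mvd by 0.43, Dhcr7 by 0.30 and the regulator gene Srebf2 by 0.28. Beside them the oligodendrocyte markers fell (3 of 13, median -0.27, adjusted p = 2.5e-04, and adjusted p = 0.751 with an estimated correlation), and these cells make much of the cholesterol of the brain. Glucocorticoid-responsive genes rose (4 of 26, 1 fell, adjusted p = 0.00415, and adjusted p = 0.412 with an estimated correlation), with Tsc22d3 at 0.30 and Klf9 at 0.27. Immediate early genes rose (2 of 19, adjusted p = 9.4e-04, and adjusted p = 0.563 with an estimated correlation), through Egr4 at 0.47 and Per1. Adjusted over the list alone, 9 clock genes rose and 1 fell, 5 glucocorticoid-responsive and 4 immediate early genes rose and 1 glucocorticoid-responsive gene, 3 cholesterol genes and 7 oligodendrocyte markers fell.

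**Figure D3:**
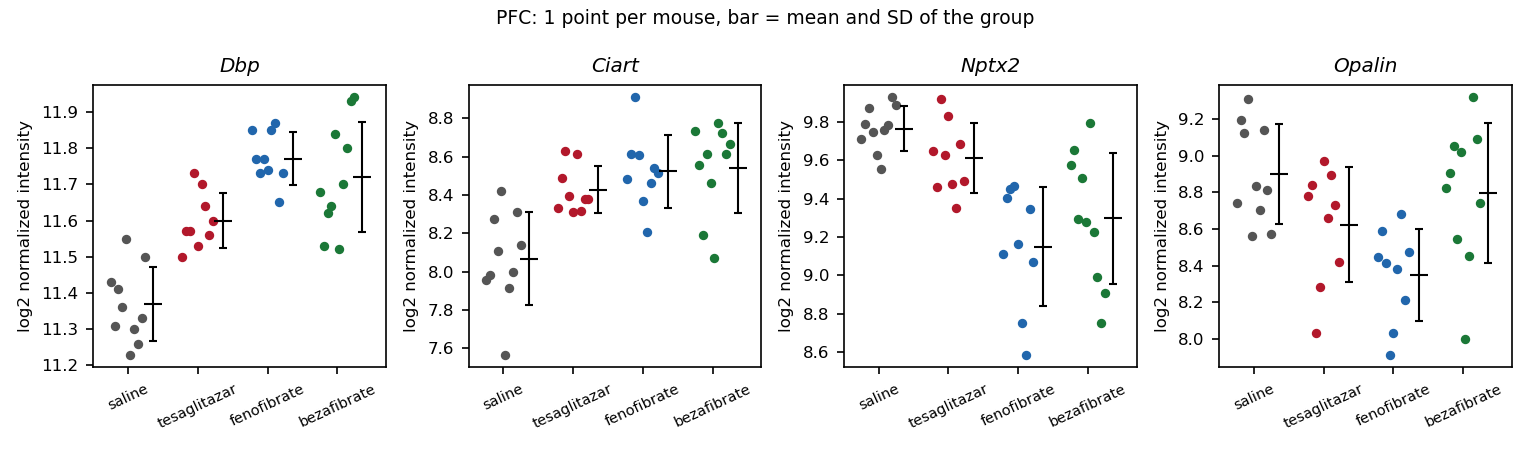
Log2 intensity of Dbp, Ciart, Nptx2 and Opalin in each PFC by treatment (9 or 10 mice per group). Points are mice and bars the mean and SD. Mean Dbp is 11.37 with saline and 11.77 with fenofibrate.

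Tesaglitazar moved no PFC gene past the limma threshold (0 of 10712 genes, 637 at an unadjusted p under 0.05). The fit recovered 92 percent of simulated changes of 0.5 on the log2 scale, but beside many changed genes and with independent noise. That share does not tell how many real changes of this size were missed. The 3 genes with the smallest p were Tsc22d3, a glucocorticoid-induced leucine zipper gene (0.39 ± 0.08 SE, adjusted p = 0.0884, 9 against 10 mice), the sulfotransferase gene Sult1a1 (0.66 ± 0.15, adjusted p = 0.13) and the ceramidase gene Acer2 (0.54 ± 0.12, adjusted p = 0.13). Without mice 4 and 6 each had an adjusted p of 0.0365, among 7 genes that rose. Glucocorticoid-responsive genes rose as a list (median 0.17, camera adjusted p = 3.3e-13, and adjusted p = 0.00203 with an estimated correlation), as did clock genes (median 0.11, adjusted p = 6.0e-06, and adjusted p = 0.00203 with an estimated correlation). Immediate early genes rose (median 0.26, adjusted p = 8.5e-07, and adjusted p = 0.369 with an estimated correlation). Adjusted over the list alone, 9 glucocorticoid-responsive, 5 clock and 1 immediate early genes rose. Blood markers fell in the same pieces (median -0.55, adjusted p = 1.3e-09, and adjusted p = 0.0236 with an estimated correlation, 4 of 6 past the threshold adjusted over the list alone), the haemoglobin gene Hbb-bt by 0.59, and so did oligodendrocyte markers (median -0.17, adjusted p = 1.7e-04, and adjusted p = 0.751 with an estimated correlation).

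Bezafibrate moved a pair of clock genes in the PFC, of 10712 tested. Dbp rose by 0.35 ± 0.05 (SE; limma adjusted p = 4.6e-04, 10 against 10 mice) and Ciart by 0.47 ± 0.09 (adjusted p = 0.0286). Neither passed when only these groups were fitted (adjusted p = 0.0845 and 0.25), and Ciart did not pass with no detection filter (adjusted p = 0.0597). Per2 rose by 0.41 ± 0.09 without passing (adjusted p = 0.138). The clock list rose (median 0.07, camera adjusted p = 6.0e-06, and adjusted p = 0.00203 with an estimated correlation), as did glucocorticoid-responsive genes (median 0.10, adjusted p = 2.1e-05, and adjusted p = 0.141 with an estimated correlation), and 5 genes of each rose adjusted over the list alone. Oligodendrocyte markers fell (median -0.12, adjusted p = 0.0224, and adjusted p = 0.751 with an estimated correlation). Of the 9 PFC tests of gene lists that passed, the 4 that held with an estimated correlation were the clock with each agonist and the glucocorticoid-responsive genes with tesaglitazar. Of the marker lists, which are not counted there, the blood markers with tesaglitazar held as well. The core PPAR targets, beta-oxidation, omega-oxidation, uptake, fatty acid synthesis, oxidative phosphorylation, NRF2, cell cycle, ethanol and aldehyde, PPAR partner, glutamate, GABA, neuropeptide, dopamine, heat shock and innate immune lists did not pass with any agonist in the PFC.

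Between agonists in the PFC, tesaglitazar exceeded fenofibrate at 478 genes and lay below it at 344, at doses that differ. Coq3, a gene of coenzyme Q synthesis, was 0.66 ± 0.13 (SE) higher on the log2 scale with tesaglitazar (limma adjusted p = 0.00276, 9 against 9 mice), the retinol transporter gene Stra6 0.63 ± 0.13 higher (adjusted p = 0.0034), Mt3 0.57 ± 0.13 higher (adjusted p = 0.00788) and Etnppl 0.55 ± 0.17 higher (adjusted p = 0.0412). The imprinted noncoding RNAs Meg3 (-0.87 ± 0.19, adjusted p = 0.00559) and Rian (-0.83 ± 0.18, adjusted p = 0.00407), with Gm7609 (-0.80 ± 0.15, adjusted p = 0.00138) and Mllt3 (-0.77 ± 0.13, adjusted p = 8.4e-04), were lower. Tesaglitazar exceeded bezafibrate at 3 genes, Stra6 (0.81 ± 0.13, adjusted p = 0.00203), Depp1 (0.75 ± 0.14, adjusted p = 0.0141) and the cholesterol 25-hydroxylase gene Ch25h (0.47 ± 0.09, adjusted p = 0.0252). Each was detected on only 3 of the 10 bezafibrate arrays, so these sizes are read against values near background. The fibrates differed at 0 genes by limma, with 1386 at an unadjusted p under 0.05. The interval for Pdk4, not adjusted over genes, was -0.39 to -0.10, and Pdk4 did not pass (adjusted p = 0.174). The correlation of log2 changes across genes was 0.228 for tesaglitazar with fenofibrate, 0.464 for tesaglitazar with bezafibrate and 0.581 for the fibrates, against 0.476, 0.462 and 0.426 by chance with shared saline arrays. Each lay inside the range of the chance draws (0.0633 to 0.762, -0.145 to 0.782 and 0.0484 to 0.808).

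No gene of 11064 passed in the amygdala by limma for any agonist against saline, with 762 genes at an unadjusted p under 0.05 for tesaglitazar, 1187 for fenofibrate and 600 for bezafibrate. With tesaglitazar the smallest p belonged to Ppp1r1b, the DARPP-32 gene of striatal neurons (0.88 ± 0.19 SE, adjusted p = 0.22, 10 against 9 mice), Pde1b (0.45 ± 0.09, adjusted p = 0.22) and Ido1, an enzyme gene of tryptophan breakdown (1.61 ± 0.37, adjusted p = 0.252). With fenofibrate they belonged to Rspo3 (-0.77 ± 0.16), Insyn2b (0.72 ± 0.16) and Dbp (0.31 ± 0.07), each with adjusted p = 0.152. With bezafibrate they belonged to Fdps, a cholesterol synthesis gene (0.63 ± 0.13, adjusted p = 0.188), Fam171a2 (-0.41 ± 0.09, adjusted p = 0.188) and Pnkd (-0.28 ± 0.07, adjusted p = 0.284). Agonists did not differ at any gene, with 540 genes at an unadjusted p under 0.05 between tesaglitazar and fenofibrate, 916 between tesaglitazar and bezafibrate and 1138 between the fibrates. Simulated changes of 0.5 on the log2 scale were recovered at 84, 78 and 88 percent for the 3 agonists against saline, with the same limit as in the PFC. Changes across genes correlated at 0.71 for tesaglitazar with fenofibrate, 0.484 for tesaglitazar with bezafibrate and 0.465 for the fibrates, against 0.502, 0.506 and 0.505 by chance. Each lay inside the range of the chance draws (-0.132 to 0.838, -0.0569 to 0.866 and 0.0128 to 0.825).

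Neuronal lists moved in the amygdala together with striatal markers. At least Tac1 is on both the neuropeptide list and the list of striatal neuron markers, so these are not separate results. Dopamine and monoamine genes rose with tesaglitazar (median 0.16, camera adjusted p = 0.00355, and adjusted p = 0.255 with an estimated correlation), Drd2 by 0.94, and with fenofibrate (median 0.16, adjusted p = 0.0474, and adjusted p = 0.333 with an estimated correlation). Neuropeptide genes rose with tesaglitazar (adjusted p = 0.0474, and adjusted p = 0.427 with an estimated correlation), Penk, the enkephalin gene, by 1.12, and with fenofibrate (adjusted p = 0.00323, and adjusted p = 0.255 with an estimated correlation), Penk by 0.90 and the tachykinin gene Tac1 by 0.68. GABA genes rose with fenofibrate (adjusted p = 0.0474, and adjusted p = 0.471 with an estimated correlation), Gad2 by 0.38. Glucocorticoid-responsive genes rose with tesaglitazar (adjusted p = 0.0209, and adjusted p = 0.481 with an estimated correlation), and core PPAR targets fell by a median of 0.06 (adjusted p = 0.0474, and adjusted p = 0.427 with an estimated correlation). Adjusted over the list alone, 6 dopamine, 2 neuropeptide and 4 glucocorticoid-responsive genes rose with tesaglitazar and 13 neuropeptide, 3 GABA and 1 dopamine genes with fenofibrate, whereas limma called 0 of them over all genes.

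Striatal neuron markers rose in the same amygdala pieces with tesaglitazar (median 0.67, camera adjusted p = 3.5e-17, and adjusted p = 0.0551 with an estimated correlation, 12 of 15 adjusted over the list alone) and with fenofibrate (median 0.53, adjusted p = 1.7e-08, and adjusted p = 0.16 with an estimated correlation, 9 of 15 adjusted over the list alone), but did not pass with bezafibrate (median 0.11, adjusted p = 0.443). Interneuron markers rose with tesaglitazar (adjusted p = 0.0126, and adjusted p = 0.225 with an estimated correlation) and fenofibrate (adjusted p = 0.00173, and adjusted p = 0.16 with an estimated correlation), and excitatory neuron markers fell with fenofibrate (median -0.22, adjusted p = 0.0166, and adjusted p = 0.14 with an estimated correlation). Oligodendrocyte markers rose with fenofibrate (median 0.20, adjusted p = 0.035, and adjusted p = 0.732 with an estimated correlation) and fell with bezafibrate (median -0.22, adjusted p = 0.00173, and adjusted p = 0.531 with an estimated correlation). Blood markers fell with tesaglitazar (median -0.32, adjusted p = 0.00173, and adjusted p = 0.16 with an estimated correlation), and choroid plexus markers rose with bezafibrate (median 0.67, adjusted p = 0.00173, and adjusted p = 0.39 with an estimated correlation). Endothelial markers fell with tesaglitazar (adjusted p = 0.0146, and adjusted p = 0.366 with an estimated correlation) and bezafibrate (adjusted p = 0.0247, and adjusted p = 0.39 with an estimated correlation).

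**Figure D4:**
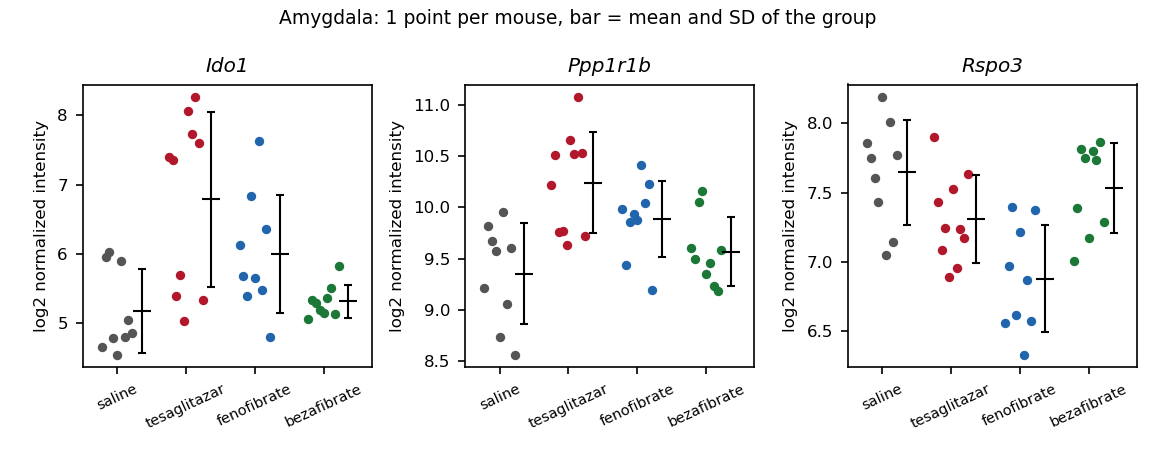
Log2 intensity of Ido1, Ppp1r1b and Rspo3 in each amygdala by treatment (9 or 10 mice per group). Points are mice and bars the mean and SD. None of the 3 genes passed, and mean Ppp1r1b is 9.35 with saline and 10.24 with tesaglitazar.

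Tests of the difference between tissues asked where each agonist acted more strongly. A gene detected in 1 of the tissues was enough for the test. In a joint fit of 112 arrays, the tesaglitazar effect differed between the liver and the mean of both brain regions at 4061 genes, 2007 of them higher in the liver, the fenofibrate effect at 2561 genes, 1388 higher, and the bezafibrate effect at 239 genes, 144 higher (390 without mice 4 and 6). Cidea, for example, differed by 5.16 ± 0.55 (SE) on the log2 scale with tesaglitazar (limma adjusted p = 3.2e-13, groups of 9 or 10 mice), Acot3 by 4.10 ± 0.40 with fenofibrate (adjusted p = 3.7e-14) and Usp2 by 1.65 ± 0.22 with bezafibrate (adjusted p = 4.6e-08). The joint fit takes a single spread per gene from all tissues, so errors are understated where the liver varies more than the brain. For Cidea and Usp2 the SE is smaller than that of the liver change alone. The counts and adjusted p for liver against brain may therefore overstate the evidence. Between the PFC and the amygdala the fenofibrate effect differed at 141 genes, 22 higher in the PFC and 119 lower. Dcn, the gene of the matrix proteoglycan decorin, differed by 1.56 ± 0.32 (0.37 in the PFC, -1.10 in the amygdala, adjusted p = 0.00507), and the vasopressin gene Avp by -1.91 ± 0.53 (adjusted p = 0.0409, but 0.0556 without mice 4 and 6). The tesaglitazar effect differed at 3 genes, each lower in the PFC, namely Ido1 (-1.55 ± 0.32, adjusted p = 0.0201), Isl1, a transcription factor gene (-1.51 ± 0.30, adjusted p = 0.0191), and Tac1 (-0.88 ± 0.19, adjusted p = 0.0337). With the mouse as a replicate block, 46 genes remained for fenofibrate, Dcn among them (adjusted p = 0.02) but not Avp (adjusted p = 0.0797), and for tesaglitazar Isl1 alone passed (adjusted p = 0.0456), Ido1 having 0.0583 and Tac1 0.0992. Avp and Isl1 were not detected on enough PFC arrays, so their differences restate an amygdala change against background that did not pass by itself. Cell markers shifted in the same amygdala pieces, so a difference in the dissected piece was not separated from a difference in response. The bezafibrate effect differed at 0 genes by limma, with 302 at an unadjusted p under 0.05.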

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

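The scores that weigh mice 4 and 6 were chosen only after their values were seen, while the tests of differences between tissues were planned. Genes of fatty acid, steroid and drug metabolism were among the largest differences between liver and brain. With tesaglitazar the change in the liver exceeded the mean change in both brain regions by 5.80 on the log2 scale for Fabp3, 5.37 for Cyp2b9, 5.16 for Cidea and 4.77 for Acot2, among 4061 genes whose effect differed. The difference was -5.83 for Hsd3b5, -4.93 for Serpina12, -3.73 for Cyp2c50 and -3.61 for Serpina1e. With fenofibrate, where 2561 genes differed, it was 5.62 for Cyp2b9, 4.10 for Acot3, 4.09 for Acot2 and 3.72 for the surface protein gene Ly6d. At the other end stood Serpina12 at -4.54, Hsd3b5 at -3.96, Serpina1e at -2.88 and the dehydrogenase gene Sdr9c7 at -2.39. Cyp2b9, Hsd3b5, Serpina12, Serpina1e, Cyp2c50, Ly6d and Sdr9c7 were not detected on enough arrays of either brain region, so their differences restate the liver change against background and show no effect in the brain. Without mice 4 and 6 no saline liver had a detected signal for Fabp3, Cidea or Ly6d, and the tesaglitazar values were 6.85 for Cyp2b9, 5.93 for Acot2, -7.32 for Hsd3b5, -6.21 for Serpina12, -4.63 for Cyp2c50 and -4.46 for Serpina1e, and with fenofibrate 6.32 for Cyp2b9, -5.15 for Serpina12 and -4.73 for Hsd3b5.

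With bezafibrate 239 genes differed between liver and brain, among them clock genes and PPAR targets. Usp2 differed by 1.65, Cyp4a14 by 1.59, Ehhadh by 1.54 and Mfsd2a by 1.48 on the log2 scale. Arntl, the clock activator gene, differed by -1.31, the tubulin gene Tubb2b by -1.22, Tmie by -1.09 and Tsc22d1 by -0.998. Cyp4a14 and Ehhadh were not detected on enough brain arrays either, so theirs is the liver change against background. Ehhadh passed here (limma adjusted p = 0.00186) although its liver change did not (adjusted p = 0.0579). The joint fit takes a single spread per gene from all tissues, which can understate errors of a liver change.

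The fenofibrate effect on Dcn, Avp and other genes differed between the PFC and the amygdala, at 141 genes in all and at 46 with the mouse as a replicate block. Higher in the PFC, Dcn differed by 1.56, the integrin gene Itga8 by 1.01, the matrix gene Fbln1 by 0.84 and the channel gene Trpc4 by 0.82 on the log2 scale. Lower in the PFC was the effect on Avp (-1.91), Tmem91 (-1.20), the glutathione peroxidase gene Gpx3 (-1.20) and the kinase gene Dgkk (-1.19). Avp and Dgkk were not detected on enough PFC arrays. Theirs is the amygdala change against background (1.96 and 1.23), which did not pass by itself (limma adjusted p = 0.2165 and 0.152). Without mice 4 and 6 the adjusted p was 0.052 for Fbln1, 0.081 for Trpc4 and 0.0556 for Avp, so that these 3 genes no longer passed. With the mouse as a replicate block, 4 of the named differences between tissues no longer passed, those of Avp, Ido1 and Tac1 among them. With tesaglitazar Ido1 (-1.55), Isl1 (-1.51) and Tac1 (-0.88) made up the 3 genes that differed, of which Isl1 alone passed with the mouse as a replicate block. Isl1 was not detected on enough PFC arrays either, and its amygdala rise of 1.47 did not pass by itself (limma adjusted p = 0.252). Ido1 and Tac1 are on the list of striatal neuron markers, which rose in the amygdala pieces with tesaglitazar, so that a difference in the dissected piece was not separated from a difference in response. Striatal, interneuron, excitatory neuron and oligodendrocyte markers also shifted in the amygdala pieces with fenofibrate, by camera at the preset correlation. The same limit therefore holds for the fenofibrate differences.

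PPAR target genes mark a pair of liver libraries that lie far from their groups. In the library labelled saline mouse 4, Cidea stood at 10.63, Cyp4a14 at 14.62, Pdk4 at 11.99 and Hsd3b5 at 4.46 on the log2 scale. In the library labelled tesaglitazar mouse 6, Cidea stood at 4.18, Cyp4a14 at 12.06, Pdk4 at 6.09 and Hsd3b5 at 11.40. The other saline livers ran from 10.76 to 12.58 for Cyp4a14 and from 5.44 to 6.51 for Pdk4, the other tesaglitazar livers from 14.33 to 14.58 and from 9.97 to 12.64. Of 104 named genes, 72 had a far sample among the saline livers, each time the library labelled mouse 4, and 53 among the tesaglitazar livers, each time the library labelled mouse 6. Chance alone gives a far sample in about 1 in 20 groups, and the bezafibrate livers had 6 of 104.

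On a liver score over 50 genes, where the other saline livers average near 0 and the other tesaglitazar livers near 1, the library labelled saline mouse 4 scored 1.02, inside the range of the tesaglitazar livers (0.876 to 1.07), and the library labelled tesaglitazar mouse 6 scored -0.00526, inside the range of the saline livers (-0.0245 to 0.0638). A missed dose in mouse 6 alone is excluded, since the library labelled mouse 4 lies 0.953 above the highest other saline liver. An exchange of the liver libraries or of their labels remains a candidate explanation, because both values it needs are there, but these data do not show at which step it took place. An exchange of the whole animals stays open, since the amygdala score (0.524 for mouse 4, 0.364 for mouse 6) put only 10 of the 17 other mice on the side of their own group. The PFC argues against it, as 15 of 18 others (83.3 percent) fell on their own side and mouse 4 at 0.311 lay inside the saline range (-0.0466 to 0.651) and below every tesaglitazar PFC (0.476 to 1.20), but both ranges overlap and mouse 6 has no PFC sample.

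Other far samples were single arrays. Usp2 was lowest in the liver of fenofibrate mouse 37, at 9.11 against 10.19 for the next, and this liver gave 10 of the 15 named genes with a far sample among the fenofibrate livers. The share of probes detected was 36.6 percent in the PFC of saline mouse 24, with the next saline array at 40.5, and 39.1 percent in the PFC of tesaglitazar mouse 28, with the next at 40.5. No explanation was tested for these 3 arrays.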

How the results depend on the processing

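Fits without mice 4 and 6, and the oligodendrocyte covariate, were chosen only after results were seen. Dbp, Hsd3b5 and the other named genes gave 9463 values under alternatives, of which 9225 kept their side of the threshold (134 of them with a change of sign of at most 1 standard error, passing in neither fit). A further 9 changed sign by more without passing, 113 stopped passing, 115 began to pass and 1 reversed with a call, Acot1 between tesaglitazar and fenofibrate in the liver, at 0.45 without mice 4 and 6. Counts of genes and lists and shared responses gave 308 values, 253 of them near the original (counts within 1.5 times) and 55 not. Among these were liver counts without mice 4 and 6 of 380 for bezafibrate against saline and 2969 for tesaglitazar against fenofibrate, PFC counts of 7 for tesaglitazar and 397 for fenofibrate, 390 for bezafibrate in liver against brain, and 4 amygdala lists. With array weights the liver counts were 3874 for fenofibrate, 375 for bezafibrate and 3225 for tesaglitazar against fenofibrate. The PFC then gave 13 for tesaglitazar, 1291 for tesaglitazar against fenofibrate and 6 between the fibrates, the amygdala 1 for bezafibrate, 2 for tesaglitazar against bezafibrate and 18 between the fibrates, and PFC against amygdala 446 for fenofibrate and 3 for bezafibrate. Variance trend and robust priors gave 1 PFC gene for tesaglitazar, 3 between the fibrates and 1 between them in the amygdala. Fits of only the groups compared have fewer arrays and gave 1 PFC gene for tesaglitazar, 153 for fenofibrate and 0 for bezafibrate by limma. No detection filter, which adds genes to the adjustment, gave 1 PFC gene for bezafibrate, 1 amygdala gene for tesaglitazar and 73 for fenofibrate in PFC against amygdala. Without background correction 3 PFC genes differed between the fibrates, 5, 250 and 1 in PFC against amygdala for tesaglitazar, fenofibrate and bezafibrate, and 3 amygdala lists passed. The processed values of the authors gave 3 PFC genes between the fibrates, 1 amygdala gene between tesaglitazar and bezafibrate, 5, 356 and 2 in PFC against amygdala, and 3 amygdala lists. The mean of the probes gave 5 PFC genes between the fibrates, and lower against upper mouse numbers as a block gave 1 amygdala gene for bezafibrate and 3 lists. With the mouse as a replicate block, PFC against amygdala had 1 gene for tesaglitazar and 46 for fenofibrate, all 46 among the 141. An estimated correlation left 0 gene lists in the liver, 4 in the PFC and 0 in the amygdala by limma's camera, and 14, 4 and 0 without mice 4 and 6. With all arrays the blood markers with tesaglitazar in the PFC, a marker list, held as well. With separate saline arrays the shared response in the PFC was -0.0470 for tesaglitazar with fenofibrate, -0.0220 for tesaglitazar with bezafibrate, both a change of sign, and 0.166 for the fibrates, and in the amygdala 0.309, 0.0577 and 0.0840, because common saline arrays no longer raise it. The oligodendrocyte covariate left 258 PFC genes for fenofibrate. Where no cause is named, the cause was not tested. The array chip as a block was not run, since the chips are not given in the sources used here. Genes whose probes were not detected above background on enough arrays, such as Cd36, Fabp4 and Vnn1, could not be tested. Whether this reflects the probes or the expression of the genes was not checked.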

Other observations

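The covariate fits, the leave-out counts, the clock shift scores and the counts of other splits were chosen after results were seen, and only the within-group clock correlation was fixed before its value was known. In the liver, some lipoprotein, stress and drug-handling genes moved without their lists passing. Of 20 apolipoprotein and lipoprotein genes, 3 rose and 10 fell with tesaglitazar (camera adjusted p = 0.107; 11 fell adjusted over the list alone). Apoa4 fell by 1.61 on the log2 scale, Apom by 1.20 and Apoc3 by 0.76, whereas the phospholipid transfer gene Pltp rose by 2.0, and fenofibrate moved Apoa4 by -1.19, Apom by -0.91 and Pltp by 1.81. The endoplasmic reticulum chaperone genes Calr and Pdia6 fell, Calr by 0.63 with tesaglitazar, 1.03 with fenofibrate and 0.75 with bezafibrate and Pdia6 by 0.58 and 0.80 with the first 2, while the mitochondrial chaperone gene Hspd1 rose by 0.76 and 0.60, so the heat shock list (10 rose and 7 fell of 28 with tesaglitazar, adjusted p = 0.63) split both ways. Glycogen and glycerol genes parted too, with Pygl at -0.70 and Gpd2 at 1.64 with tesaglitazar (6 rose and 10 fell of 22, adjusted p = 0.385). Among CAR and PXR targets 6 rose and 12 fell of 25 with tesaglitazar (adjusted p = 0.0874), Gadd45b at 2.18 and Cyp2c29 at -1.99, and Cyp2b10 rose by 1.28 with fenofibrate. Adh7 rose by 1.12 and Adh4 fell by 1.06 with tesaglitazar in an ethanol and aldehyde list whose median (-0.01) and test differ in sign. Ncoa3, a coactivator gene of the PPARs, fell by 0.88 with tesaglitazar and 0.56 with fenofibrate, and the omega-oxidation gene Cyp4f14 fell by 3.24 with tesaglitazar (-4.07 without mice 4 and 6; 8 rose and 3 fell of 12, adjusted p = 0.107). Innate immune genes did not pass in the liver (5 rose and 6 fell of 36 with tesaglitazar, adjusted p = 0.789). Median, mean and test differed in sign only in lists that did not pass, such as apolipoprotein genes with fenofibrate and endothelial markers with tesaglitazar in the liver.

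Single genes of fat metabolism fell in the PFC with fenofibrate, although none of the lists they come from passed there. By limma 0 uptake and lipid droplet genes rose and 3 fell of 25, of core PPAR targets 0 and 2 of 23, of mitochondrial beta-oxidation genes 0 and 2 of 29 and of peroxisomal genes 1 and 1 of 29. Acot3 fell by 0.32 (limma adjusted p = 0.0208), Pdk4 by 0.27 (adjusted p = 0.0233), Dgat1 by 0.28 (adjusted p = 0.0126), Cideb by 0.33 (adjusted p = 0.038) and the fatty acid transporter gene Slc27a1 by 0.27 (adjusted p = 0.0314). Acot3 rose in the liver, and the difference between liver and brain was 4.10. Neuronal genes moved in the same PFC arrays, with the vesicular glutamate transporter gene Slc17a7 at -0.28 (adjusted p = 0.0237) and the NMDA receptor gene Grin2a at 0.36 (adjusted p = 0.0242), as did Maob at -0.21, Ndufa12 at -0.28, Stat3 at 0.39 and the myelin genes Cnp at -0.43 and Fa2h at -0.52. Excitatory neuron, interneuron, astrocyte, microglia, endothelial, striatal and hippocampal or thalamic markers did not pass as lists with any agonist in the PFC, nor did astrocyte, microglia and hippocampal or thalamic markers in the amygdala. In the amygdala the clock list missed the threshold with tesaglitazar (adjusted p = 0.0536). In the liver the microglia or macrophage, endothelial, blood and stellate cell lists did not pass, although 5 of 6 blood markers fell with tesaglitazar (median -0.42, adjusted p = 0.142).

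The PFC changes with fenofibrate, such as those of Dbp, Nptx2 and Opalin, were weighed against technical explanations. Fenofibrate mouse 20 alone as their source is excluded, since 554 genes passed without it. The number of calls does depend on single arrays, with 377 genes without saline mouse 3, 388 without fenofibrate mouse 38, 397 without saline mouse 4 and 449 without fenofibrate mouse 40. Also excluded is the share of probes detected, which averaged 41.3 percent with fenofibrate and 41.1 percent with saline and as a covariate left the log2 changes of the called genes at a median ratio of 0.997. Less myelin in the pieces was weighed by the oligodendrocyte marker mean, 9.34 ± 0.25 (SD, n = 9) against 9.64 ± 0.24 (SD, n = 10). That mean as a covariate left the changes at a median ratio of 0.942, which argues against less myelin as the source of the called genes as a set. A median over all called genes does not speak for myelin genes such as Opalin. With that covariate only 258 genes passed, 228 of them among the 678, as the median standard error grew from 0.0739 to 0.0805 beside a median change of 0.28. An effect of fenofibrate on the PFC may remain, as a hypothesis, beside the open question of the clock.

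The clock list rose in the PFC with every agonist. Dbp passed with both fibrates, whereas no single gene passed with tesaglitazar when all arrays were used. A clock score was compared with saline, the mean of genes such as Dbp and Per2 minus the mean of genes of the opposite phase (Arntl, Clock, Npas2, Cry1 and Nfil3, of which 2 or 3 were measured). It shifted by 0.218 ± 0.0645 (SE) with tesaglitazar, 0.403 ± 0.0645 with fenofibrate and 0.325 ± 0.0627 with bezafibrate in the PFC. A later or earlier hour of killing than in the saline mice may explain the fenofibrate shift, since without mice 4 and 6 it was 4.63 standard errors in the liver, 5.95 in the PFC and 2.97 in the amygdala, all in 1 direction. For bezafibrate the liver moved by 6.26 standard errors and the amygdala by only 1.68, and for tesaglitazar the liver moved by -1.87, so neither can be told apart from an effect of the drug on the clock, which stays open for all 3 agonists. Within groups the PFC and amygdala scores of the same mouse gave r = 0.211 over 35 mice (permutation p = 0.332, rho = 0.288 with permutation p = 0.117, 0.14 without the 2 farthest mice, adjusted p = 0.332 over the 3 pairs of tissues), which does not decide whether mice of a group differed in hour.

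For the other pairs of tissues the clock scores gave r = 0.278 over 36 mice for liver and PFC (permutation p = 0.0841, adjusted p = 0.252, rho = 0.264 with permutation p = 0.123, 0.294 without the 2 farthest mice) and r = -0.214 over 34 mice for liver and amygdala (permutation p = 0.204, adjusted p = 0.306, rho = -0.238 with permutation p = 0.173, -0.104 without the 2 farthest mice). In the liver fenofibrate moved 6 of 16 clock genes up and 3 down (adjusted p = 0.385), Usp2 by 2.0, Per2 by 0.96, Arntl by -0.90 and Nr1d1 by -0.84.

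Fatty acid genes such as Cidea and Acot2 in the liver stand on counts that other groupings of the same mice did not match. In each test 100 splits into groups of the same sizes were used, the real one among them. Chance can be excluded for tesaglitazar against saline (4385 genes, 1 of the 100 splits, highest other 2606), fenofibrate (2486, 1, highest other 153) and bezafibrate (158, 1, highest other 7), and for tesaglitazar against fenofibrate (1782, 1, highest other 710), tesaglitazar against bezafibrate (4425, 1, highest other 2736) and the fibrates (2019, 1, highest other 362). Splits that call 2606 or 2736 genes point to a structure among the livers, and a split that keeps most mice of 1 treatment together carries part of its effect.

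Dbp, Ciart, Stra6 and the other genes that passed in the PFC rest on smaller counts. There chance can be excluded for the counts of fenofibrate (678 genes, 1 of 100 splits, highest other 167) and tesaglitazar against fenofibrate (822, 1, highest other 154). For tesaglitazar against bezafibrate (3, 1, highest other 1) no other split called as many genes. The margin is small and the 3 genes lay near background with bezafibrate, so chance is less likely but not excluded. For bezafibrate 4 of the 100 splits gave at least the 2 genes found (highest other 114). So few such splits make chance less likely for the count but do not exclude it, and neither gene passed when only these groups were fitted. A split with 114 genes points to some structure of the samples, though only 3 of the other splits called any gene. Where the real count is 0, each of the 100 splits is as large by construction, so the splits say nothing about chance. This holds for tesaglitazar (0 genes by limma, 637 at an unadjusted p under 0.05, highest other 1) and between the fibrates (0, 1386 unadjusted, highest other 17). In the amygdala, where Ppp1r1b, Pde1b and Ido1 had the smallest p with tesaglitazar without passing, it holds for every comparison, each with 0 genes by limma and all 100 splits as large. The highest other split gave 284 genes for tesaglitazar, 218 for fenofibrate, 448 for bezafibrate, 195 for tesaglitazar against fenofibrate, 282 for tesaglitazar against bezafibrate and 1 between the fibrates. The larger of these counts beside 0 point to some structure among the amygdala samples, though at most 6 of the other splits called any gene in a comparison. The unadjusted counts were 762, 1187, 600, 540, 916 and 1138 in the same order.

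Between tissues, Cidea, Acot3 and Usp2 were among the genes that differed. Chance can be excluded for the count of tesaglitazar in liver against brain (4061 genes, 1 of 100 splits, highest other 2310). Another split exceeded the real count for fenofibrate (2561, 2 of 100, highest other 2637) and for bezafibrate (239, 2 of 100, highest other 293) in liver against brain. So few such splits make chance less likely for these 2 counts but do not exclude it. Of the other splits, 55, 49 and 64 called some gene in the same order, which points to structure among the samples. In PFC against amygdala chance can be excluded for the fenofibrate count, not for any single gene (141, 1 of 100 splits, highest other 52, and 46 with the mouse as a replicate block). With tesaglitazar (3 genes, 2 of 100 splits, highest other 10, and 1 gene with that block) another split called more genes, so chance is not excluded. For bezafibrate in PFC against amygdala the real count is 0 by limma (302 at an unadjusted p under 0.05), so all 100 splits are as large by construction and say nothing about chance. The highest other was 217, which points to some structure, and 12 of the other splits called any gene.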
